A study of Mus musculus with 6 samples.

How the data were processed

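Total RNA was extracted with Trizol and libraries were made with an Illumina TruSeq RNA kit, per the labels' protocols; this kit does not mark strand, so reads from overlapping antisense genes cannot be told apart. The 6 libraries cover 2 states (NSC and differentiated, labelled D2) and 3 ligand conditions (control, naloxone, DAMGO), with 1 library per group, passage 8 throughout. The authors deposited a table per library with an expected count, a TPM and an FPKM value for each gene. Per the submitters' processing notes the tools were Bowtie and RSEM and the genome build was mm10; versions, the annotation and read filters are not given in the sources used here. Expected counts are the deposited estimates that divide reads mapping to several genes or transcripts, and TPM values, also deposited by the authors, are scaled to the same total in each library. The FPKM column was not used. The tables held 29267 Ensembl gene identifiers, of which 28756 matched GENCODE release M21 on the same build, from which symbols and coordinates were taken. Identifiers without a match are named by their identifier. Most ribosomal protein genes and the genes of the mitochondrial genome were not analysed here.

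Expected counts were rounded to whole numbers, which moved a library's total by at most 46.1 counts. Totals were 10674127, 13561237 and 9112916 counts in the NSC libraries (control, naloxone, DAMGO) and 10218353, 8417074 and 8809642 in the D2 libraries. A gene with 0 counts in a library may have had up to 3 counts, which is 0.221 to 0.356 CPM. Intervals and such floors cover counting error only. Chi-square values per degree of freedom between libraries of the same state were 1.59 to 1.86 in NSC and 4.05 to 4.23 in D2, so no library was a copy of another.

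Genes with a mean of at least 10 counts over the 6 libraries were tested (13216 genes, at least 99.8% of each library's counts). Counts were normalised by TMM and fitted with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest) in an additive model of state and ligand, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The 2 residual degrees of freedom hold library noise together with any ligand effect that differs between the states. The common biological coefficient of variation was 0.0529 and the prior degrees of freedom were 9.45. Gene lists were written before the data were examined: 28 lists with 577 entries, of which 23 were tested with camera in limma 3.58.1 (preset correlation 0.01, Benjamini-Hochberg over lists within a contrast). Camera with an estimated correlation and fry were alternatives. Fry asks whether the members of a list move together and does not compare them with other genes. The ribosomal protein list was left out because only 2 of its 27 genes were matched. The lists of opioid receptors and peptides, microglia and macrophages, ependymal cells and pluripotent cells had fewer than 3 tested members. Their summed levels over the 6 libraries were 83.0 to 189 CPM, 1.57 to 5.84 CPM, 7.83 to 30.8 CPM and 2.26 to 16.8 CPM.

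Comparisons within a state involve 2 libraries and carry no p-value. They are given as log2 ratios of TMM-normalised CPM with a prior count of 2, with exact binomial 95% intervals of the count ratio. List medians are placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. Correlations between comparisons that share a control were set beside 100 simulations of unchanged libraries. GC content per gene was the mean over GENCODE M21 transcripts and was available for 99.4% of tested genes and all 23 cholesterol genes; trends were fitted with natural splines on GC content and log2 length over 10997 genes of at least 5 CPM.

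Named genes followed a rule fixed before the data were examined. For state it took the 10 largest rises and falls among genes past the threshold with the same direction in all 3 ligand conditions and at least 5 CPM. For each ligand contrast it took all called genes, and the 5 highest and 5 lowest by the smaller of the ratios in the 2 states. Within a state it took the 5 highest and 5 lowest of at least 20 CPM, all without names of predicted genes, microRNAs or clones. From each list discussed up to 4 changed members, or up to 2 of the most abundant, were named, and opioid receptors, TET genes and Mki67, Nes, Tubb3 and Gfap always. Collagen genes, S100a6, H19 and other genes high in the D2 control library, and genes of region and sex, were chosen after their values were seen, as were a few further list members given as examples.

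The scripts were tested on simulated data, counts with the real means, library sizes and dispersions. In a simulated naloxone contrast over 13216 genes, 74.6% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 97.0% of those changed 4-fold were recovered, and 13 unchanged genes were called. In a simulated state contrast the shares were 77.6%, 86.6% and 97.0%, with 22 unchanged genes called. Apart from the simulated changes, each gene had the same mean level and dispersion in both states. No simulated ligand effect differed between the states, so these shares need not hold for the real contrasts. Alternatives were DESeq2 1.42.0 size factors, the DESeq2 Wald test, no filter, a mean of at least 100 counts, limma on log2(TPM + 1), a 2-fold limit, a model of state alone, libraries left out, other prior counts and other axis limits. Those chosen after seeing the data were leaving out each library in turn, removal of the trend on GC content and length, and restriction to genes with whole-number expected counts.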

Results

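RNA sequencing measured gene expression in cultured mouse neural stem cells of the OG2 line at passage 8. Cells were profiled as neural stem cells, called NSC below, or after differentiation, under a label that reads D2. In each state there were 3 libraries: a control without ligand, 1 with naloxone, an antagonist of opioid receptors, and 1 with DAMGO, a peptide agonist of the mu opioid receptor. Each of the 6 groups held 1 library, so no group had a replicate, and the labels do not say whether the libraries came from separate cultures. Totals ranged from 8417074 expected counts in D2 with naloxone to 13561237 in NSC with naloxone, and 17124 to 17850 genes had a count in each library. The series asks how naloxone affects proliferation and differentiation of these cells. State was compared over the 3 ligand conditions and each ligand over the 2 states, in an additive model with 2 residual degrees of freedom. Its p-values measure only the spread between these 6 libraries. Comparisons within 1 state are values of 2 libraries with no replicate check.

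The classical opioid receptors were at the limit of detection. Oprm1 (chromosome 10, 6758506 to 7038198, mm10), the mu receptor and the target of DAMGO, had 0 counts in all 6 libraries. With a floor of 3 counts over the 6 libraries together, this allows a level of up to 0.0493 CPM, for counting error only. The delta receptor Oprd1 and the kappa receptor Oprk1 had 2 counts each over the 6 libraries. The nociceptin receptor Oprl1 rose from 2.10 ± 0.671 CPM (SD over the 3 ligand conditions) in NSC to 19.1 ± 1.22 CPM in D2, and its edgeR log2 fold change was 3.22 (SE 0.20, adjusted p = 1.47e-08). Ogfr, the opioid growth factor receptor, which is unrelated in sequence to the classical receptors, rose from 81.0 ± 0.859 to 164 ± 6.13 CPM (edgeR log2 fold change 1.02, SE 0.05, adjusted p = 5.08e-09). Neither Oprl1 nor Ogfr passed the test for naloxone or DAMGO.

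Differentiation changed most expressed genes, and transcripts of cell cycle genes fell. Of 13216 genes tested, 5287 rose and 5256 fell in D2 against NSC (edgeR, adjusted p under 0.05), of which 2097 and 2379 did so by at least 2-fold. The direction was the same in all 3 ligand conditions for 10460 of the 10543. That is not a separate check, since the test takes its error from the spread of the same 3 differences. The proliferation marker Mki67 (chromosome 7, 135689784 to 135716361) fell from 1518 ± 37.5 to 31.1 ± 9.44 CPM (edgeR log2 fold change -5.64, SE 0.12, adjusted p = 2.07e-12). Nes, which encodes the intermediate filament of neural progenitors, fell from 1837 ± 16.5 to 405 ± 8.68 CPM (log2 fold change -2.18, SE 0.04). Tubb3, a tubulin of young neurons, rose from 11.9 ± 1.43 to 104 ± 4.33 CPM (log2 fold change 3.13, SE 0.08), and Gfap, an astrocyte filament, rose from 0.179 ± 0.0732 to 9.69 ± 2.46 CPM (log2 fold change 5.67, SE 0.31). The first principal component of log2 CPM held 91.9% of the variance and separated NSC from D2.

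**Figure D1:**
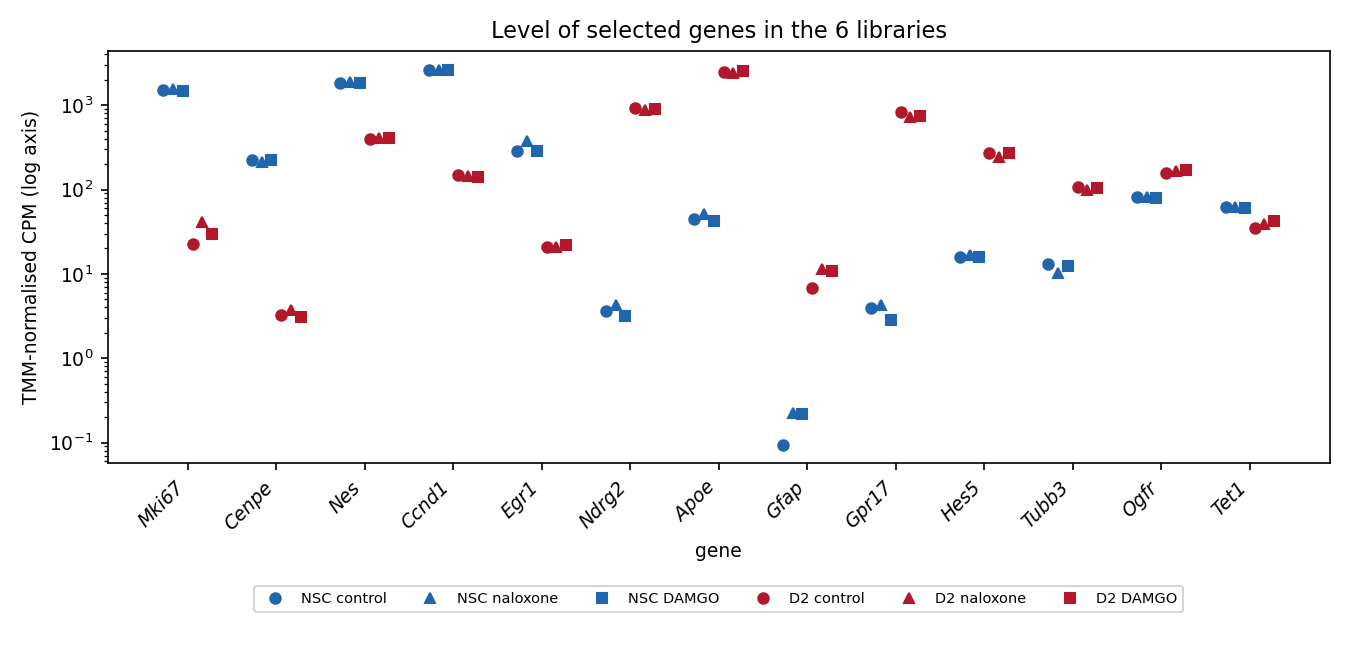
Level of 13 genes in each of the 6 libraries, as TMM-normalised CPM on a log axis; each point is 1 library, blue for NSC and red for D2, with the symbol giving the ligand condition. Mki67, Nes and Ccnd1 lie lower in all 3 D2 libraries than in the NSC libraries, and Ndrg2, Apoe and Gpr17 lie higher.

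The genes with the largest rises included markers of glial lineages. Ndrg2 (chromosome 14, 51905271 to 51914158), an astrocyte-enriched gene, rose from 3.69 ± 0.553 to 900.5 ± 30.6 CPM (log2 fold change 7.90, SE 0.08). Gpr17 (chromosome 18, 31942997 to 31949636), a receptor of immature oligodendrocytes, rose from 3.71 ± 0.746 to 765 ± 54.8 CPM (log2 fold change 7.65, SE 0.09). Lrtm2 had 2 counts over the NSC libraries and 527 over the D2 libraries, a 318-fold ratio with an exact 95% counting interval of 87.6 to 2632. Pdzph1 had 2 and 333 counts, a 201-fold ratio with an interval of 55.2 to 1666. Abhd3, Lipg, a lipase gene, Prdm16, a transcriptional regulator, Tmem132b, Ccdc190 and Dhrs3, a retinaldehyde reductase gene, rose with log2 fold changes between 6.41 and 7.39. The largest falls were those of Adamts14 (log2 fold change -6.98, SE 0.30), Cd93 (-6.64, SE 0.16), Itga4, an integrin subunit (-6.35, SE 0.10), Scml4 (-6.35, SE 0.22), Kif20b, a kinesin of dividing cells (-6.31, SE 0.14), Dgkg (-6.09, SE 0.35), the kinetochore motor Cenpe (-6.04, SE 0.09), Clic5 (-5.86, SE 0.16), the activity-regulated gene Arc (-5.71, SE 0.21) and Mki67. All 20 genes named for their large changes had an edgeR adjusted p of at most 9.35e-09.

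Cell cycle genes fell as a block. All 25 tested genes of G2/M and mitosis fell (median log2 fold change -3.06), with Cenpf at -5.31 (SE 0.09) and the checkpoint kinase Bub1 at -4.83 (SE 0.09). All 26 genes of DNA replication and S phase fell (median -2.90), among them the cyclin Ccne2 at -4.85 (SE 0.13), the polymerase subunit Pola1 at -4.39 (SE 0.09) and the replication licensing factor Cdt1 at -3.58 (SE 0.10). The limma camera adjusted p was 1.01e-48 for the G2/M list and 1.47e-31 for the replication list, and the adjusted p was 0.207 for each with an estimated correlation. Of 21 p53 targets, 15 fell and 2 rose (median -0.80; camera in limma, adjusted p = 6.67e-05, and adjusted p = 0.284 with an estimated correlation). The members that fell most were Gtse1, which is itself active in G2 (-3.29, SE 0.08), the cell cycle inhibitor Cdkn1a (-2.92, SE 0.06), Pidd1 (-2.63, SE 0.10) and Plk2 (-2.40, SE 0.06). Of 18 ERK pathway targets, 12 fell and 3 rose (median -0.93; camera in limma, adjusted p = 0.0190, and adjusted p = 0.508 with an estimated correlation). Ccnd1, the G1 cyclin, fell from 2628 ± 16.8 to 145 ± 5.38 CPM, the feedback inhibitor Spry4 fell by 2.60 and the phosphatase Dusp4 fell by 2.34 on the log2 scale, whereas Epha4 rose (2.41, SE 0.08). Of 21 immediate early genes, 16 fell and 3 rose (median -1.67; camera in limma, adjusted p = 0.0333, and adjusted p = 0.324 with an estimated correlation). Egr1 fell from 314 ± 50.7 to 21.4 ± 0.741 CPM, and Egr4 (-3.28, SE 0.54) and Egr3 (-3.19, SE 0.37) fell from low levels.

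Astrocyte genes rose together and oligodendrocyte genes rose in part. All 19 tested astrocyte genes rose (median log2 fold change 3.09; camera in limma, adjusted p = 1.19e-29, and adjusted p = 0.146 with an estimated correlation). Apoe, the main brain apolipoprotein, rose from 45.6 ± 4.60 to 2480 ± 89.4 CPM, the secreted chaperone Clu from 1.86 ± 0.301 to 70.8 ± 4.16 CPM, and the water channel Aqp4 from 1.23 ± 0.746 to 47.0 ± 5.01 CPM. Of 16 genes of the oligodendrocyte lineage, 12 rose and 3 fell (median 0.66; camera in limma, adjusted p = 1.55e-06, and adjusted p = 0.207 with an estimated correlation). Besides Gpr17, the lineage factor Sox10 (5.50, SE 0.18), the progenitor receptor Pdgfra (4.83, SE 0.08) and the myelin enzyme Cnp (2.76, SE 0.06) rose. Of 20 Notch pathway genes, 14 rose and 2 fell (median 1.39; camera in limma, adjusted p = 8.48e-08, and adjusted p = 0.207 with an estimated correlation), with the ligand Dll3 at 4.19 (SE 0.06), the target Hey2 at 4.04 (SE 0.37), the target Hes5 at 4.01 (SE 0.07) and the receptor Notch3 at 2.79 (SE 0.08). In the list of neural stem cell and progenitor genes, which shares Hes1, Hes5, Lfng and Notch1 with the Notch list, 17 of 24 rose and 6 fell. Tnc, a matrix protein of the stem cell niche (-3.56, SE 0.06), Hmga2 (-3.22, SE 0.12) and Nes were among those that fell. That list did not pass the camera test in limma (adjusted p = 0.0982). Among 23 neuronal genes 12 rose and 7 fell, with Dcx at 2.88 (SE 0.08), Dlx2 at 2.71 (SE 0.20) and the growth cone gene Gap43 at -3.48 (SE 0.07), and the list did not pass (camera in limma, adjusted p = 0.490).

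Cholesterol synthesis genes fell: 20 of 23 fell and 3 did not pass (median -0.75; camera in limma, adjusted p = 1.80e-05, and adjusted p = 0.273 with an estimated correlation). The isomerase Idi1 fell by 2.55, Stard4 by 1.52 and Ebp by 1.31 on the log2 scale. Among 21 genes of DNA methylation and demethylation, 10 fell and 6 rose, and the list did not pass (camera in limma, adjusted p = 0.360). The maintenance factors Uhrf1 (-3.53, SE 0.06) and Dnmt1 (-2.05, SE 0.05) and the deaminase gene Apobec3 (-1.24, SE 0.09) fell, and Gadd45g rose (2.42, SE 0.09). Of the TET dioxygenases, Tet1 fell from 61.1 ± 0.722 to 38.7 ± 3.45 CPM (edgeR log2 fold change -0.67, SE 0.07, adjusted p = 4.17e-06). Tet3 fell slightly (-0.17, SE 0.05; edgeR, adjusted p = 0.00717), a call lost with limma on log2(TPM + 1). Tet2 did not pass (-0.07, SE 0.07; edgeR, adjusted p = 0.392). Of 17 partners of opioid receptor signalling, 7 rose, such as the adenylyl cyclase Adcy8 (2.78, SE 0.09) and the G protein Gnao1 (2.67, SE 0.07), and 7 fell, such as Creb1 (-1.86, SE 0.06).

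**Figure D2:**
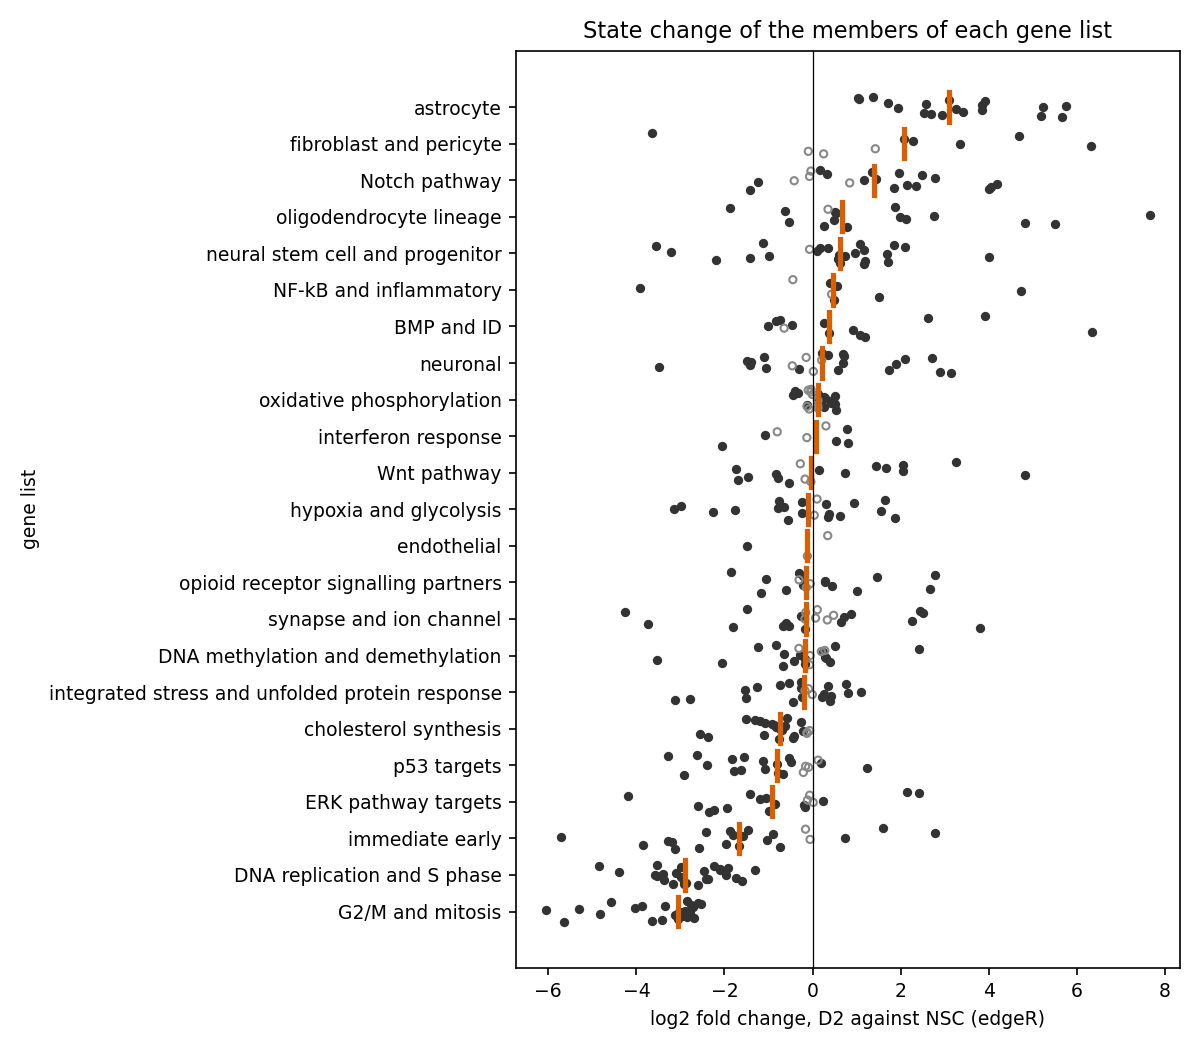
Log2 fold change of each tested member of the 23 gene lists in D2 against NSC from edgeR; filled points passed the adjusted p threshold, open points did not, and the orange bar is the list's median. G2/M and replication genes lie below 0 throughout and astrocyte genes lie above 0 throughout.

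The other lists did not pass the camera test in limma (adjusted p between 0.135 and 0.989). Members rose and fell as follows: BMP and ID, 8 and 4 of 13 (Id4 at 6.35, SE 0.15). Wnt pathway, 8 and 6 of 17. Synapse and ion channel, 7 and 10 of 23 (Gria1 at 3.81, SE 0.12, and Camk2b at -4.25, SE 0.06). Integrated stress and unfolded protein response genes rose in 8 cases and fell in 11 of 22, hypoxia and glycolysis genes in 8 and 10 of 20, and oxidative phosphorylation genes in 12 and 4 of 25. Interferon response genes rose in 3 cases and fell in 2 of 8, and genes of the NF-kB and inflammatory list in 5 and 1 of 8 (Vcam1 at 4.74, SE 0.07). Without the NSC library with DAMGO or the D2 library with DAMGO 1 interferon gene fell, and without the D2 library with naloxone 3 genes of the NF-kB list rose. Of 3 endothelial markers 0 rose and 1 fell, while 1 rose without the NSC control or without the D2 control and 0 fell without the NSC library with DAMGO. Of 9 fibroblast and pericyte markers, 5 rose, such as Pdgfrb (6.32, SE 0.41) and Myl9 (4.68, SE 0.18), and Fbln2 fell (-3.64, SE 0.08); 8 rose without the NSC library with naloxone or without the D2 library with naloxone, and 3 fell without the NSC control or without the D2 control. The camera direction was up while the median was below 0 for the opioid signalling list (-0.14) and the Wnt list (-0.04), and the interferon list had a median of 0.09 with a mean of -0.21. Adjusted over the list alone, each list kept the same numbers of members that rose and fell. The edgeR count of changed genes lay between 9917 and 10173 when a library or a pair of libraries was left out. Without 1 library, the other library of its ligand no longer bears on the state contrast. The runs without 1 library therefore nearly repeat those without a pair and are not separate checks. The camera test called 9 lists with its preset correlation and 0 with an estimated correlation. The estimated correlation was 0.438 for the G2/M list but -0.0288 for the astrocyte list, below the preset 0.01. The camera p of the astrocyte list still rose from 1.55e-30 to 0.00633. A call lost in this setting thus does not by itself show that correlation between members made the result.

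The edgeR test called very few genes for the ligands over the 2 states, and those few are poorly characterised. For naloxone against control, 2 of 13216 genes passed the edgeR test. The gene with the identifier ENSMUSG00000103627 was higher with naloxone, with 38 and 44 counts in NSC and D2 against 0 in the controls, at least 25.8-fold with 3 counts as the floor over the pair of controls (adjusted p = 0.0193). Gm28042 had 41 and 89 counts in the control libraries and 0 in all 4 ligand libraries, at least 45.8-fold lower with naloxone (edgeR, adjusted p = 0.0141) and at least 37.3-fold lower with DAMGO (edgeR, adjusted p = 0.0102). For DAMGO, Gm28042 and Gm21738 passed. Gm21738 had 1002 counts in D2 with DAMGO, 210 in the D2 control and at most 6 in any NSC library (edgeR log2 fold change 2.37, SE 0.21, adjusted p = 0.00155). Between naloxone and DAMGO, 4 genes passed: Gm26669, which was higher with naloxone, and Gm21738, Gm10801 and DXBay18, which were lower. The lower genes differed mainly in 1 state each. Gm21738 had 3 counts with naloxone against 4 with DAMGO in NSC and 92 against 1002 in D2. Gm10801 had 1 against 2 in NSC and 56 against 420 in D2, and DXBay18 had 0 against 49 in NSC and 0 against 1 in D2. All 6 called genes had fractional expected counts, meaning that reads were divided between features, so their values are uncertain. The number of genes at an unadjusted p under 0.05 was 293 for naloxone, 317 for DAMGO and 280 for the difference, against 661 by chance, and DESeq2 called 1, 0 and 0 genes. Numbers below chance mean that the edgeR test was conservative here. Its residual also holds any ligand effect that differs between the states, so few calls do not mean few changes. With NSC and D2 libraries of different ligands paired instead, 15 contrasts called 1 to 21 genes, with a median of 5, so the real counts were no higher than those of wrong pairings. The same 15 contrasts called a median of 2 gene lists and up to 6, against at most 2 in the real pairing. The edgeR counts moved with each library left out. For naloxone, DAMGO and their difference they were 74, 123 and 33 without the NSC control, 39, 25 and 20 without the NSC library with naloxone, and 11, 46 and 37 without the NSC library with DAMGO. They were 26, 16 and 26 without the D2 control, 1, 4 and 5 without the D2 library with naloxone, and 9, 4 and 5 without the D2 library with DAMGO. For genes of at least 20 CPM the median half-width of the 95% interval of a ligand log2 fold change was 0.18.

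Genes with the same direction in both states are given as values, since none passed the edgeR test except those above. With naloxone, BC037034 had an additive log2 fold change of 1.77 and was at 32.5 against 7.16 CPM in D2. Cd72, Catsper2, Itih3 and Pla2g4b had additive log2 fold changes of 1.18 (SE 0.36), 0.74 (SE 0.26), 0.65 (SE 0.19) and 1.02 (SE 0.26). The lowest included Tom1, with 143 against 196 counts in NSC but 0 against 317 in D2, and Pgk1-rs7, with 119 against 131 counts in NSC but 0 against 104 in D2. The others were Cldn10, a tight junction gene (-0.85, SE 0.26), Tmem17 (-0.46, SE 0.23) and Tmem267 (-0.45, SE 0.20). Counts of 0 beside high counts also occurred in 4 of the 6 called genes, whose reads were divided between features. Whether read division made the zeros of Tom1 and Pgk1-rs7 was not tested. With DAMGO, Lsm7, a splicing factor gene (1.98, SE 0.73), Degs2 (0.71, SE 0.23), Nhs (0.63, SE 0.23), Hspa1l (0.58, SE 0.25) and Gsdme (0.56, SE 0.19) were highest. Fam189b (-0.52, SE 0.16), St3gal6 (-0.56, SE 0.23), Tbc1d30 (-0.57, SE 0.23), Vat1l (-0.61, SE 0.24) and Pgk1-rs7 were lowest, and Pgk1-rs7 had 0 CPM in both DAMGO libraries against 12.4 and 10.2 CPM in the controls. Between naloxone and DAMGO, Snurf (0.84, SE 0.22), Thbs1 (0.81, SE 0.24), Pcdha12 (0.75, SE 0.25), Vat1l (0.68, SE 0.24) and Fam189b (0.54, SE 0.15) were highest, and Tom1 (143 against 282 counts in NSC and 0 against 125 in D2), Hist2h2aa2 (-0.80, SE 0.50), Tmem25 (-0.51, SE 0.24), Prrg2 (-0.46, SE 0.24) and Hist3h2ba (-0.39, SE 0.21) were lowest.

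Cholesterol synthesis genes stood apart with naloxone, by small amounts. In the additive model 21 of 23 members had a negative log2 fold change for naloxone against control, with a median of -0.09 (camera in limma, adjusted p = 6.16e-07, and adjusted p = 0.705 with an estimated correlation). No single member passed the edgeR test, also when adjusted over the list alone. Hmgcs1, an early enzyme of the pathway, was at 1530 CPM with naloxone against 1597 in NSC and at 1114 against 1197 in D2. Srebf2, the transcription factor of the pathway, was at 507 against 529 CPM in NSC and at 421 against 450.4 in D2. For DAMGO the list's median was -0.05 with 18 of 23 negative (camera in limma, adjusted p = 0.0340, and adjusted p = 0.690 with an estimated correlation). The ERK pathway targets had a median of -0.06 with naloxone, with 14 of 18 negative (camera in limma, adjusted p = 0.0203, and adjusted p = 0.705 with an estimated correlation). Among them Ccnd1 had a log2 fold change of -0.02 (SE 0.05) and Etv5 of -0.21 (SE 0.08). The fibroblast and pericyte list was lower with DAMGO (median -0.26; camera in limma, adjusted p = 0.0340, and adjusted p = 0.690 with an estimated correlation) and higher with naloxone than with DAMGO (median 0.17, 9 of 9 positive; camera in limma, adjusted p = 0.0104, and adjusted p = 0.906 with an estimated correlation). The latter difference lay in NSC, with a median of 0.81 and 8 of 9 higher, whereas in D2 the median was -0.03 with 4 of 9 higher. Its members Fbln2 and Thy1 did not pass the edgeR test for either ligand.

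Within NSC the ligand libraries were close to the control. For naloxone, 96 of 13216 genes differed by at least 2-fold with a counting interval that excluded equality, of which 1 had at least 20 CPM, and the SD of the log2 ratio over such genes was 0.09. The immediate early genes Fos, at 42.7 against 31.1 CPM (log2 ratio 0.46, interval 0.26 to 0.66), and Egr1, at 372 against 286 CPM (0.38, interval 0.32 to 0.45), were among the highest, with Igfbp5 (0.46), Ptges2 (0.39) and Pmm2 (0.37). The lowest were Tmem121 (-0.37), Ppp2r3d (-0.37), Adi1 (-0.35), Cyp20a1 (-0.34) and Golph3l (-0.33). The median of the immediate early list was 0.15, at the 99.6th percentile of 10000 matched random lists, with 17 of 21 members higher. Of 19 astrocyte genes 17 were higher with a median of 0.10, above all 10000 random lists, and Sparcl1 was at 484 against 458 CPM. Of the BMP and ID list 10 of 13 were higher (median 0.12, percentile 99.5). Of 23 cholesterol synthesis genes 20 were lower (median -0.06), below all 10000 random lists. All 9 fibroblast and pericyte markers were higher (median 0.60, percentile 99.97), such as Col1a2 at 4.22 against 0.378 CPM. With naloxone in D2 the immediate early, astrocyte and BMP and ID lists lay at percentiles 43.2, 49.1 and 44.1, so their shifts were not seen again there.

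For DAMGO in NSC, 106 genes differed by at least 2-fold, of which 2 had at least 20 CPM. The highest were Tom1 (log2 ratio 0.74, interval 0.48 to 1.02), Timmdc1 (0.59), Igfbp5 (0.43), Nxn (0.40) and St7l (0.40), and the lowest were Gemin4 (-0.63, interval -0.91 to -0.36), Zbed6 (-0.59), Add2 (-0.43), the class I histocompatibility gene H2-K1 (-0.41) and Hmga1b (-0.39). The p53 targets (median -0.08, percentile 0.45) and the oligodendrocyte list (median -0.10, percentile 0.31) lay low and the integrated stress list lay high (median 0.05, percentile 98.9). Of the fibroblast and pericyte markers 8 of 9 were lower (median -0.56, percentile 0.06), but the median was -0.06 with TPM. Mki67 was at 1532 CPM in the NSC control, 1546 with naloxone and 1475 with DAMGO, and Nes was at 1823, 1855 and 1831 CPM.

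**Figure D3:**
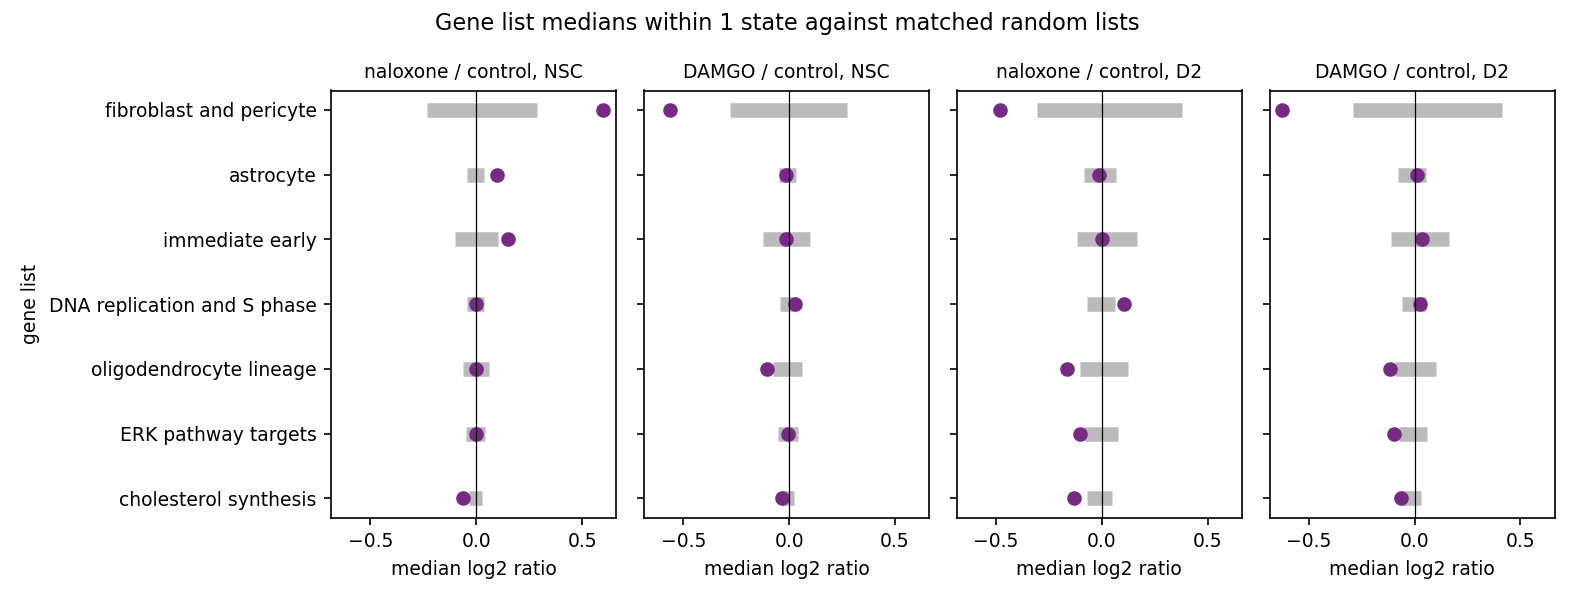
Median log2 ratio of 7 gene lists (points) for each ligand against control within each state, with the central 95% of 10000 random lists matched on expression (grey bars). Cholesterol synthesis genes lie below the bar with naloxone in NSC (-0.06) and in D2 (-0.13).

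Within D2 the libraries differed more. For naloxone, 174 genes differed by at least 2-fold, 8 of them at 20 CPM or more, and the SD of the log2 ratio was 0.18. Of the genes with at least 20 CPM, the lowest were the secreted phosphoprotein Spp1, at 3 counts against 622 (log2 ratio -6.79, interval -9.71 to -5.87), fibronectin, Fn1, at 11.1 against 55.4 CPM (-2.30), the transcription factor Foxo1 at 29.8 against 61.0 CPM (-1.03, interval -1.25 to -0.82), Hmga1b (-0.74, but 0.90 on the log2(TPM + 1) scale) and Ccdc85c (-0.69). Tom1, with a lower mean, had 0 counts against 317, and whether read division made this zero was not tested. The highest were Lars2, a mitochondrial tRNA ligase gene, at 300.3 against 106 CPM (log2 interval 1.40 to 1.61), Arhgap5 (0.94), Mki67 at 41.1 against 22.4 CPM (0.87, interval 0.63 to 1.13), Zfp932 (0.84) and Mpp5 (0.72). DNA replication genes were higher in 19 of 26 cases (median 0.11, percentile 99.8), such as Rrm1 at 135 against 116 CPM. G2/M genes were higher in 16 of 25 cases, but their median of 0.05 lay inside the central 95% of random lists (percentile 92.5). Oligodendrocyte genes were lower in 13 of 16 cases (median -0.16, percentile 0.09), such as Olig1 at 3561 against 3983 CPM and Olig2 at 1050.2 against 1213 CPM. Cholesterol synthesis genes were lower in 21 of 23 cases (median -0.13), below all 10000 random lists, ERK targets in 13 of 18 (median -0.10, percentile 0.70) and progenitor genes in 15 of 24 (median -0.09, percentile 0.37). Notch genes were lower (median -0.09, percentile 1.83) and integrated stress genes higher (median 0.09, percentile 99.2). In NSC with naloxone the replication, oligodendrocyte, ERK, progenitor, Notch and integrated stress lists lay at percentiles 53.3, 54.1, 54.0, 90.3, 11.6 and 56.5. Each of these was inside the central 95%. For naloxone in D2 the log2 ratio fell with GC content across genes (Spearman rho -0.475, genes not being independent replicates). After removal of a smooth trend on GC content and length, 6 of the 8 lists outside the central 95% of random lists stayed outside, and the oligodendrocyte and Notch lists did not.

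For DAMGO in D2, 220 genes differed by at least 2-fold, 15 of them at 20 CPM or more. Spp1, with 3 counts against 622 (log2 ratio -6.83, interval -9.77 to -5.94), Fn1 (-2.34, interval -2.70 to -2.05), Foxo1 (-1.48, interval -1.73 to -1.25), Tom1 (-1.13) and B2m, the light chain of class I molecules (-0.54), were lowest. The nuclear RNA Malat1 was at 621 against 278 CPM (1.16, interval 1.10 to 1.23), followed by Fgd4 (0.94), Rorb (0.83), Naa15 (0.67) and the antisense RNA Kcnq1ot1 (0.66). G2/M genes lay low (median -0.08, percentile 0.70), with 18 of 25 lower, while Mki67 was at 29.8 CPM. Oligodendrocyte genes (median -0.12, percentile 0.80), ERK targets (median -0.10, percentile 0.34) and cholesterol synthesis genes (median -0.07, percentile 1.95) also lay low. After removal of the trend on GC content and length the cholesterol synthesis list lay at percentile 2.99, inside the central 95%. In NSC with DAMGO the G2/M, ERK and cholesterol synthesis lists lay at percentiles 71.8, 54.1 and 4.88, and the oligodendrocyte list at 0.31. With the trend removed, the cholesterol synthesis list with DAMGO in NSC lay outside the central 95%, at percentile 0.18 (median -0.04). In D2 the fibroblast and pericyte list was lower than in the control library with naloxone (median -0.48, percentile 0.34) and with DAMGO (median -0.62, percentile 0.11, and a median of -0.21 with TPM). Gfap was at 6.87 CPM in the D2 control, 11.3 with naloxone and 10.9 with DAMGO, Tubb3 at 107, 99.0 and 105 CPM, and Nes at 395, 411 and 408 CPM.

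Naloxone against DAMGO within a state leaves out the control libraries. In NSC the astrocyte (median 0.08, percentile 99.8), oligodendrocyte (0.10, percentile 99.4), immediate early (0.20, percentile 99.9), p53 target (0.06, percentile 98.8, and 89.6 after removal of the trend on GC content and length) and fibroblast and pericyte lists (0.81, percentile 99.99) lay high, and the hypoxia and glycolysis list lay low (-0.05, percentile 2.32). In D2 the G2/M list (0.19, above all 10000 random lists) and the replication list (0.11, percentile 99.9) lay high, and the cholesterol synthesis list lay low (-0.11, percentile 0.01). Over the 138 pairs of a list and a within-state comparison, 31 lay outside the central 95% of random lists, which does not allow for correlation between members or between comparisons that share libraries, and 27 of the 31 stayed outside on the same side after removal of the trend on GC content and length. After that removal 34 pairs lay outside, among them p53 targets for naloxone in D2 (percentile 0.96, from 9.84). Some sizes moved as well. For naloxone against DAMGO the median became 0.06 for replication genes in D2 and -0.08 for hypoxia and glycolysis genes in NSC. For p53 targets with DAMGO in NSC the median became -0.05. The sign of all 31 medians was the same with DESeq2 size factors and with TPM, but several sizes moved by over 1.5 times with TPM. For naloxone in D2 the medians with TPM were -0.08 for cholesterol synthesis, -0.04 for Notch and 0.16 for replication genes. They were -0.07 for oligodendrocyte genes with DAMGO in D2 and -0.04 for p53 targets with DAMGO in NSC. For naloxone against DAMGO they were -0.06 for cholesterol synthesis in D2, and 0.02 for p53 targets and -0.02 for hypoxia and glycolysis genes in NSC.

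**Figure D4:**
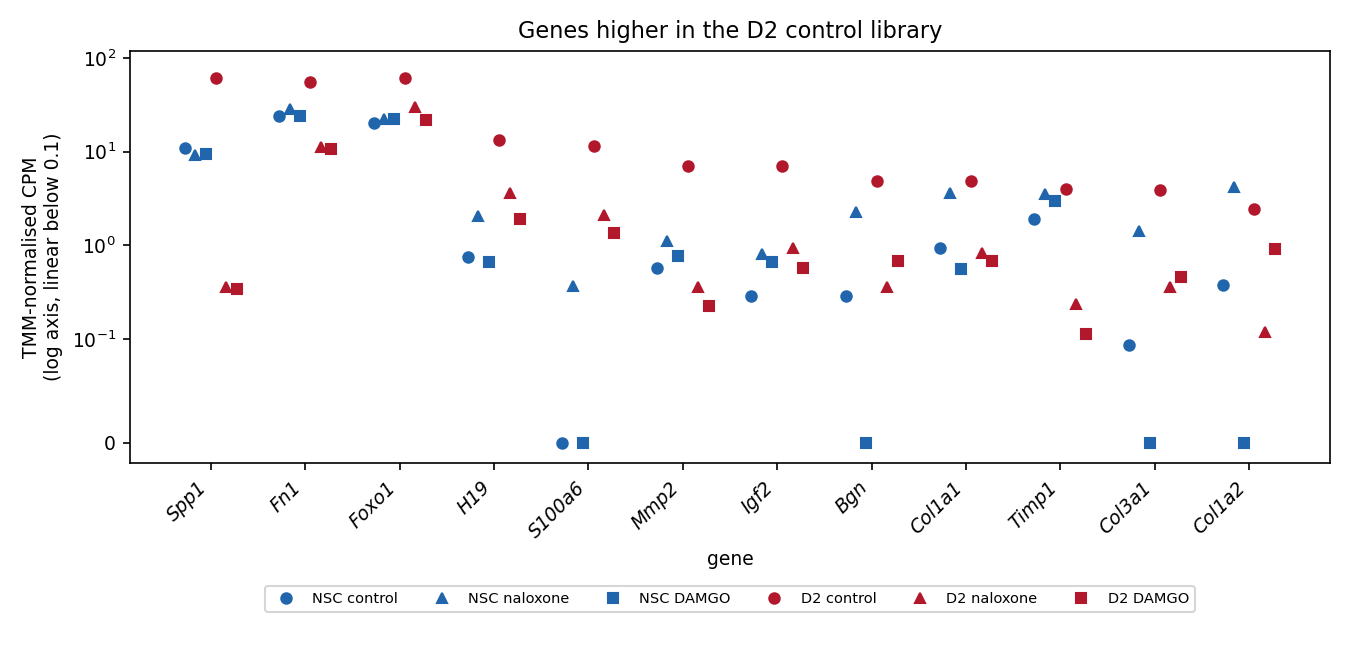
Level of 12 genes in the 6 libraries, as TMM-normalised CPM on an axis that is logarithmic above 0.1 and linear below; each point is 1 library. In D2 all 12 lie higher in the control library, with Spp1 at 61.0 CPM against 0.354 with naloxone and 0.340 with DAMGO.

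The ligand ratios of the 2 states did not go together across genes. The correlation of the log2 ratio in NSC with that in D2 was -0.0480 for naloxone and -0.0425 for DAMGO (Pearson r over 13216 genes, which are not independent replicates), and the Spearman values were -0.0583 and -0.00932. Pairing naloxone in NSC with DAMGO in D2 gave -0.0820 and the reverse pairing gave 0.0120. Within a state, naloxone and DAMGO ratios share the control library. Their correlation was 0.483 in NSC, where unchanged libraries with a shared control gave 0.506 on average in 100 simulations, and the covariance differed from the simulated value by 0.000547. In D2 the correlation was 0.574 against a simulated 0.476, and the covariance was higher than the simulated value by 0.0387. The simulations used 1 dispersion per gene for both states, with mean covariances of 0.0420 in NSC and 0.0417 in D2. Real libraries differed more in D2 (chi-square per degree of freedom 4.05 to 4.23) than in NSC (1.59 to 1.86). The simulated covariance may thus be too high for NSC and too low for D2, so the excess in D2 cannot be read as a change shared by the ligands. With a single control library the excess also cannot be split from the control itself.

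Along the axis of differentiation, taken from the pair of libraries of the other ligand, the larger shifts were those of falling genes in D2. In D2 with naloxone, the 2369 genes that fall at least 2-fold with differentiation had a median log2 ratio 0.12 above that of all genes, and 66.4% of them were higher than in the control. The 2160 rising genes had a median of -0.03 relative to all genes. With DAMGO in D2 the falling genes had a median of 0.06 and the rising genes of -0.02. In NSC the values were 0.03 for rising and -0.02 for falling genes with naloxone and at most 0.01 in size with DAMGO. After removal of the trend on GC content and length the values in D2 were 0.04 for falling and -0.00 for rising genes with naloxone, and 0.03 for falling genes with DAMGO. The shifts of both ligands in D2 use the same single control library. That library lay furthest toward D2 on the first principal component, at 77.3 against 70.8 with naloxone and 74.2 with DAMGO. The shifts thus cannot be told apart from a difference of the control.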

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

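With 1 library per group no rule for outlying samples applied, and each difference between NSC and D2 given here comes from a ratio of 2 libraries in each state; the differences were not tested. Of the tests in this part, those on RNA from fibroblast-like cells, on ligand-free culture, on a ligand effect in D2 alone, on the trend with GC content and length, and on the control libraries were chosen after the result was seen, as were removal of the trend and the runs without single libraries.

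The median of the fibroblast and pericyte list for naloxone against control was 0.60 in NSC and -0.48 in D2, a difference of -1.08 on the log2 scale. Ptges2 had log2 ratios with naloxone of 0.39 in NSC and -0.40 in D2, a difference of -0.79. Lars2 had -0.18 in NSC and was higher in D2, a difference of 1.68. Fn1 had 0.24 and -2.30, a difference of -2.54. Malat1 had -0.06 and 0.53 with naloxone, a difference of 0.59, and -0.14 and 1.16 with DAMGO, a difference of 1.30. Tom1 had 0.74 and -1.13 with DAMGO, a difference of -1.87. Mki67 had -0.05 and 0.41 with DAMGO, a difference of 0.46. With naloxone Mki67 had 0.01 in NSC and a larger ratio in D2, 0.87. It was not flagged there because the rule for genes needed opposite directions in the 2 states, each with a counting interval that excluded equality.

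In the D2 control library 34 genes were at least 2-fold above both other D2 libraries, 26 of them without predicted names, among them Spp1 (61.0 CPM against 0.354 and 0.340), Mmp2 (7.06 against 0.354 and 0.226), S100a6 (11.6 against 2.13 and 1.36) and H19 (13.4 against 3.66 and 1.92). Several were extracellular matrix genes, such as Fn1 (55.4 against 11.1 and 10.8), Col1a1 (4.81 against 0.827 and 0.679), Col1a2, Col3a1 and Bgn. Others, such as Foxo1 and Tom1, were not. Ligand-free culture as a cause in both states may be questioned but stays open: 23.1% of the 26 genes were highest in the NSC control, the median log2 ratio there was -0.64 with an interquartile range of 1.14, and Col3a1, S100a6 and Bgn were near the floor. In NSC some matrix genes of the pattern were highest with naloxone instead. Col1a1 was at 3.62 CPM there against 0.944 in the control and 0.551 with DAMGO, and Col1a2 at 4.22 against 0.378 and 0. Spp1 was highest in the NSC control, at 10.9 CPM against 9.24 with naloxone and 9.48 with DAMGO. RNA from fibroblast-like cells may be a source, and the test on fibroblast genes decides neither way. The median of 16 of them lay at the 88.5th percentile of random lists, with 8 of 16 higher. These 16 remained of 30 chosen genes after untested genes and any genes of the pattern itself were left out. Leaving out genes of the pattern works against finding a shift. Sparc, at 320.4 CPM against 354 and 327 in D2, was also at 130 to 145 CPM in NSC, so it says little on fibroblast RNA. The fibroblast genes were picked after the pattern was seen, and Tagln, Acta2 and Thy1 among them belong to the list in which it was seen. An effect of both ligands in D2 alone cannot be told apart from a difference of the single control culture, since D2 has 1 library without ligand.

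Cholesterol synthesis genes were lower with naloxone in both states. A trend on GC content and transcript length is argued against as the whole cause, since after its removal the medians were -0.07 in NSC and -0.14 in D2 and the higher of their percentiles was 0, below all 10000 random lists. High control libraries alone could contribute: naloxone against DAMGO, which leaves the controls out, gave a percentile of 0.01 in D2 but 2.99 in NSC, inside the central 95%. In the 15 contrasts of other pairings of NSC and D2 libraries, 0 gave a camera p as small as the real 2.68e-08 (the smallest was 5.38e-06), but 8 gave a p under 0.05; some of these keep part of the naloxone ratio, and 18 contrasts are too few for a share under 0.05. An effect of naloxone on this pathway is a hypothesis that these libraries leave open, with an adjusted p of 0.705 with an estimated correlation in limma.

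The 6 genes called in the ligand contrasts may reflect reads shared between overlapping or near-identical genes. All 6 had fractional expected counts in at least 1 library, against 42.4% of all tested genes (one-sided Fisher's exact p = 0.00577), and 4 of them had 0 counts in some libraries and at least 10 in others. Among the 41 genes with the smallest p in any ligand contrast 87.8% had fractional counts. Restriction to the 7618 genes with whole-number expected counts removes all 6 by construction and adds nothing on the cause; edgeR called 0 of the remaining genes for naloxone, DAMGO and their difference, with 139, 140 and 121 at an unadjusted p under 0.05. A ligand effect on these genes was not tested apart from that.

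Other splits of the 6 libraries into 3 and 3 decide nothing about the state results. The real split gave 10543 changed genes and the highest of the other 9 gave 0, with 1 of 10 splits giving as many. For the number of gene lists past the camera threshold, the real split gave 9 and the highest other gave 10, with 6 of 10 splits giving as many. The 10 splits are too few for a share under 0.05, and each other split sets 2 libraries of 1 state against 1, so part of the state difference stays in its contrast and part enters its residual; neither count is a value for no change.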

How the results depend on the processing

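Leaving out single libraries, the trend removal and the restriction to whole-number counts were chosen after seeing the data, that is after the result was seen. For 28 genes named in the state contrast, 413 of 414 alternative values kept direction and side of the threshold, and the Tet3 call was lost with limma on log2(TPM + 1) (log2 difference -0.17). The 414 values include runs without 1 library, which nearly repeat the runs without a pair of libraries. The count of genes changed with state was 4476 with a 2-fold limit, a stricter criterion by construction, and 9917 to 10173 with libraries left out; all other alternatives lay within 1.5 times of 10543. For naloxone, DAMGO and their difference, in this order, the main counts of 2, 2 and 4 became 0, 2 and 1 with DESeq2 size factors, 1, 0 and 0 with the DESeq2 Wald test, 45, 83 and 53 with no filter, 0, 1 and 1 at a mean of at least 100 counts, 0, 0 and 0 with limma on log2(TPM + 1), 11, 3 and 27 with only the 4 libraries compared, and 0, 0 and 0 with whole-number counts, which removes every called gene by construction. With 1 library left out, which leaves 1 residual degree of freedom, they ranged from 1 to 74, 4 to 123 and 5 to 37, highest without the NSC control for naloxone (74) and DAMGO (123) and without the NSC library with DAMGO for the difference (37). Lists past the threshold numbered 9 for state, 2 for naloxone, 2 for DAMGO and 1 for their difference with the preset correlation, 0 for each with an estimated correlation, and 20, 0, 0 and 0 with fry, which asks another question; DESeq2 size factors gave 4 for the difference. The adjusted p of the cholesterol list with naloxone (limma camera) was 0.705 with an estimated correlation, 0.537 with fry, 7.93e-07 with DESeq2 size factors and 3.72e-06 to 0.00210 with libraries left out. Genes beyond 2-fold for naloxone in NSC, DAMGO in NSC, naloxone in D2 and DAMGO in D2 numbered 206, 200, 404 and 437 beyond 1.5-fold, 39, 48, 79 and 106 with a prior count of 10, and 54, 66, 104 and 129 on log2(TPM + 1); the first is looser by construction. The correlation between states for DAMGO was -0.105 and that of both ligands in D2 was 0.529 at a mean of at least 100 counts. The shift of falling genes in D2 with naloxone was 0.0446 with the GC content and length trend removed, from 0.12. Hmga1b reversed to 0.90 for naloxone in D2 on log2(TPM + 1); the cause was not tested. Where not stated by construction, the cause of the other moves was not tested either. No paired analysis was possible because each group holds replicate 1 alone, beyond the block of ligand in the state contrast, without which 10710 genes changed.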

Other observations

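Region and sex genes give further values on these cultures. The forebrain factors Emx2 (33.5 ± 2.24 CPM in NSC and 38.9 ± 2.27 CPM in D2, SD, n = 3) and Lhx2 (69.6 ± 2.18 and 187 ± 12.9 CPM) were expressed in every library, and of the midbrain and hindbrain factors En1 and Hoxa2 had at most 2 counts in any library while En2 was at 1.65 ± 0.296 and 1.29 ± 0.419 CPM. Other forebrain factors were as low: Otx2 was at 1.38 ± 0.536 and 1.93 ± 0.331 CPM, Six3 at 0.984 ± 0.130 and 1.06 ± 0.0754 CPM, and Nkx2-1 had at most 3 counts in any library. These genes were chosen after the result was seen. Lhx2 rose with differentiation (edgeR log2 fold change 1.42, SE 0.06, adjusted p = 4.74e-10), and Gbx2 fell from 4.49 ± 0.795 to 1.47 ± 0.369 CPM (edgeR, adjusted p = 0.000305). The X inactivation RNA Xist was at 1779 ± 43.0 CPM in NSC and 836 ± 156 CPM in D2, and the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were detected in the same libraries. Xist fell (edgeR log2 fold change -1.11, SE 0.08, adjusted p = 1.24e-07), as did Ddx3y (-2.82, SE 0.16), Uty (-1.41, SE 0.14) and Eif2s3y (-0.52, SE 0.10), while Kdm5d did not pass (0.07, SE 0.09; edgeR, adjusted p = 0.458).

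The D2 library with DAMGO had 43 genes at least 2-fold above both other D2 libraries, of which 35 had names of predicted genes. Gm21738 was at 113 CPM there against 20.6 in the D2 control and 10.9 in D2 with naloxone, and Gm10801 at 47.5 against 10.4 and 6.62 CPM. The numbers of such genes were 34 in the D2 control, 10 in D2 with naloxone, and 14, 15 and 10 in the NSC libraries with no ligand, naloxone and DAMGO.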
